A study of Mus musculus with 37 samples.

How the data were processed

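RNA sequencing of mouse liver was analysed from 1 deposited table of 55487 genes in 37 libraries, covering 10 groups of WT and Nox4 knockout mice after partial hepatectomy or sham operation. The values were taken to be expected counts as deposited, since the authors' processing notes name STAR 2.5.3a and RSEM 1.3.0 with the mouse genome GRCm38, without saying which tool made the counts. The notes do not give the annotation release, the strand setting or any filter, and the whole numbers in the table were taken to be rounded RSEM estimates. Genes that overlap on opposite strands or have close paralogs therefore have less certain values. The labels give no strain, age, time of day or sequencing batch.

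Total counts ranged from 26232544 to 48827025 per library. Gene names and positions came from GENCODE release M21, in which 55227 identifiers matched, and 234 genes shared a symbol with another. The sex given in the labels was checked against sex-linked transcripts and matched in every library. Replicates of a group were checked for duplicates, and the closest pair differed by a chi-square of 32.07 per degree of freedom over genes with at least 20 counts.

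Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (15564 genes) were scaled by TMM and fitted in 1 robust quasi-likelihood model of all 37 libraries, with the 10 groups and sex as additive terms (common biological coefficient of variation 0.39). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and SE is the log2 change divided by the square root of the F statistic. The contrasts were each stage after hepatectomy against sham within a genotype, KO against WT at each stage, the genotype by hepatectomy interaction at each stage, and KO against WT averaged over the stages. Sham livers taken at different times were pooled within each genotype.

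Gene lists fixed before the data were examined, 36 of processes and 15 of cell types, were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2, and again with an estimated correlation. List p-values were adjusted over all the lists of a comparison. The exocrine pancreas list had 1 tested gene and was not interpreted. S-phase and G2/M scores were means of log2(CPM + 1) over the list, compared between genotypes by two-sided exact permutation tests with Benjamini-Hochberg adjustment over the 5 stages of each score.

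Named genes followed a rule fixed before the data were examined. It took Nox4 first, then up to 6 genes with the largest change in each direction among those past the threshold with a mean of at least 5 CPM in the higher group and ranges that did not overlap (overlap was not asked for interactions and averages). It then took the members with the smallest p of the described lists, and a fixed panel of regeneration and metabolism genes. Of the genes so named, the text gives mostly those whose call held when each library was left out. Their stability therefore follows in part from this choice and does not show that a comparison as a whole was stable. Results for some of the genes so named are not reported here, and these genes were left out of the check for libraries far from their group. For genes with at most 3 counts in the reference group, CPM values are given in place of a fold change, or beside it for the interaction of Fosl1.

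The alternatives chosen before the data were examined were DESeq2 1.42.0, RLE scaling, no count filter beyond 1 count, no sex term, a fit of the compared groups alone, male libraries alone and leaving out each library in turn. Correction for GC content and gene length, for the 99.86% of genes with a GC value, and leaving out the 6 h sham livers were added after the data were seen. A fit of the compared groups alone does not apply to the average over stages, which uses all groups. The procedure was tested on simulated data in which 200 genes were changed in the study's own design. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of lower genes was not measured. Genes were drawn independently around a common mean, with no outlying liver, so recovery in the real data may differ. Of the 4-fold changes it recovered 77% in the KO to WT comparison at 24 h and 83% at 48 h, and of the 2-fold changes 25% and 34%. At 7 d it recovered 14% of the 2-fold and 68% of the 4-fold changes between the genotypes. The interaction tests at 6 h, 24 h, 48 h and 7 d recovered 7%, 4%, 5% and 0% of the 2-fold changes and 47%, 53%, 64% and 52% of the 4-fold changes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. No library was left out of the table.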

Results

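Gene expression was measured by RNA sequencing in 37 liver libraries from wild-type (WT) mice and from mice lacking Nox4 (knockout, KO), an NADPH oxidase that produces hydrogen peroxide. The mice had undergone partial hepatectomy, the surgical removal of most of the liver mass, or a sham operation. The study's stated question is whether loss of Nox4 changes the pace of liver regeneration. The WT libraries comprised 5 sham livers and 3, 3, 4 and 3 livers taken 6 h, 24 h, 48 h and 7 d after hepatectomy. The KO libraries comprised 5 sham livers and 3, 4, 4 and 3 livers at the same times. Sham livers formed 1 group per genotype although they were taken at mixed times, 7 d, 48 h, 24 h, 48 h and 6 h for WT replicates 1 to 5 and 24 h, 48 h, 48 h, 72 h and 6 h for KO replicates 1 to 5. All 6 h hepatectomy livers were from males, and the other groups held both sexes. Total counts per library ranged from 26232544 to 48827025. P-values here measure the spread between these libraries, which the labels call separate samples without naming the animals.

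The first principal component of log2 expression held 26.1% of the variance. Scores lay between 61.2 and 91.0 in the 6 libraries taken 6 h after hepatectomy. The 6 h sham livers stood at 40.9 in the WT and 19.3 in the KO, above the other sham livers. Among the KO 24 h livers, replicates 1 to 4 scored -26.8, 90.6, 122 and 98.0, while WT 24 h replicates 1 to 3 scored -25.8, -32.8 and 0.66. WT 48 h replicate 3 stood at 25.2, with S-phase and G2/M scores of 1.93 and 0.425, below the other WT 48 h livers.

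**Figure D1:**
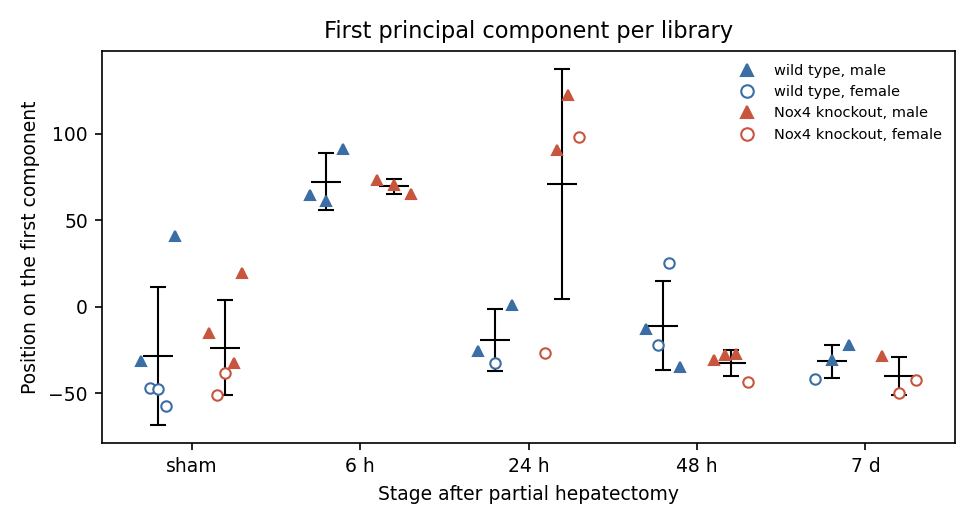
First principal component score (vertical axis, no unit) of each of the 37 libraries by stage (horizontal axis), WT in blue and KO in red, triangles for males and open circles for females; bars give the mean ± SD of each group. The KO 24 h libraries lie at -26.8, 90.6, 122 and 98.0, and the WT 24 h libraries at -25.8, -32.8 and 0.66.

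Nox4 (ENSMUSG00000030562, chromosome 7, 87246096 to 87398710, plus strand, GRCm38) was lower in the KO, and its level also depended on sex. In WT sham replicates 1 to 5 it stood at 18.7, 3.36, 1.43, 1.29 and 19.1 CPM (counts scaled by library size). In the WT after hepatectomy it was 22.9, 7.92 and 23.2 CPM at 6 h, 8.06, 0.778 and 23.5 CPM at 24 h, 3.95, 1.80, 1.12 and 14.4 CPM at 48 h, and 1.24, 10.1 and 4.50 CPM at 7 d. In KO sham replicates 1 to 5 it was 4.57, 0.153, 0.224, 4.98 and 2.40 CPM. In the KO after hepatectomy it was 2.31, 3.05 and 1.55 CPM at 6 h, 0.0352, 0.325, 1.69 and 0 CPM at 24 h, 2.74, 2.07, 1.21 and 0.245 CPM at 48 h, and 4.31, 0.196 and 0.0268 CPM at 7 d. Male livers averaged 14.2 ± 7.62 CPM in the WT (SD, n = 11) and 2.60 ± 1.42 CPM in the KO (SD, n = 12). Female livers averaged 1.57 ± 0.846 CPM in the WT (SD, n = 7) and 0.126 ± 0.103 CPM in the KO (SD, n = 7). With sex in the model, Nox4 was lower in the KO by a log2 change of -2.82 (SE 0.28, edgeR quasi-likelihood adjusted p = 4.27e-08) averaged over the stages, and higher in males by 3.58 (SE 0.34, adjusted p = 2.67e-09). By stage it was lower at sham (-2.66, SE 0.53, adjusted p = 0.0114), 24 h (-4.07, SE 0.69, adjusted p = 0.000885) and 48 h (-2.60, SE 0.60, adjusted p = 0.041), and did not pass at 6 h (-2.95, SE 0.66, adjusted p = 0.0577) or 7 d (-1.81, SE 0.67, adjusted p = 1). The averaged call held whichever library was left out. The sham call was lost without the sex term, in males alone, without the 6 h sham livers and without KO sham replicate 3. The 24 h call was lost in a fit of the 2 groups alone. That at 48 h was lost without the sex term, in males alone, in a fit of the 2 groups alone and without WT 48 h replicates 2, 3 or 4 or any KO 48 h replicate. At 6 h it passed by DESeq2, without the count filter, with GC and length correction and without KO 6 h replicate 2, and at 7 d without the count filter. Within females the ranges of the genotypes did not overlap, a separation that chance gives in 0.0583% of groupings. Among males, KO sham replicates 1 and 4 and KO 7 d replicate 1 lay above the lowest WT male at 3.95 CPM. The counts cover the whole gene and the deleted exons are not given, so the residual counts do not show whether a functional transcript remained.

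**Figure D2:**
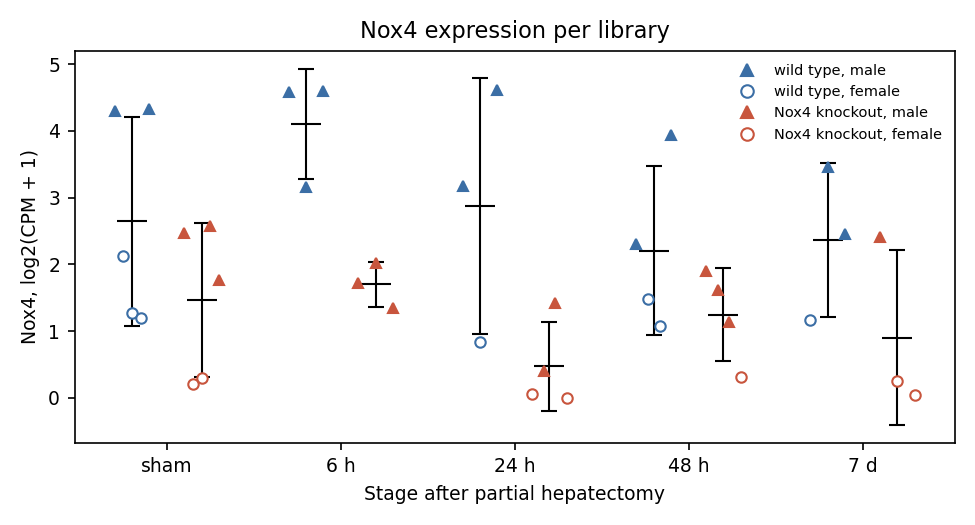
Nox4 expression as log2(CPM + 1) (vertical axis) in each library by stage (horizontal axis), WT in blue and KO in red, triangles for males and open circles for females; bars give the mean ± SD of each group. WT males averaged 14.2 CPM and KO males 2.60 CPM, WT females 1.57 CPM and KO females 0.126 CPM.

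Early response and inflammatory genes were among those that rose in the WT 6 h after hepatectomy. Sham livers were pooled over mixed times, with only replicate 5 of each genotype taken at 6 h. Effects of hepatectomy at 6 h are therefore not separated from those of time after surgery. Against sham livers (n = 5), 1223 genes changed at 6 h (n = 3), of which 647 rose and 576 fell, and 1032 changed at least 2-fold. Il1rn, the interleukin-1 receptor antagonist, rose by 3.90 on the log2 scale (SE 0.65, adjusted p = 0.000769), the stress transcription factor Atf3 by 3.78 (SE 0.64) and the early response gene Ier3 by 3.39 (SE 0.66). Pdk4, a kinase that restrains pyruvate oxidation, rose by 7.68 (SE 1.5), the lipid droplet protein gene Hilpda by 4.89 (SE 0.95) and the cholesterol hydroxylase gene Ch25h by 4.49 (SE 1.0). Genes that fell included the growth arrest gene Gas1 at -4.31 (SE 0.82), Fam13a at -3.86 (SE 0.84), the fructose transporter gene Slc2a5 at -3.75 (SE 0.86) and Tbc1d30 at -3.43 (SE 0.66).

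Of 20 immediate early genes, 10 rose and the others did not pass (18 higher adjusted over the list alone). The list ranked high among all genes by camera (adjusted p = 6.55e-14, and adjusted p = 0.227 with an estimated correlation). Of 14 inflammatory cytokine and NF-κB genes, 7 rose (12 adjusted over the list alone), among them the NF-κB feedback inhibitor Tnfaip3 by 2.46 (SE 0.51) and the monocyte chemokine Ccl2 by 3.09 (SE 0.75). Camera gave adjusted p = 5.54e-08, and 0.227 with an estimated correlation. Of 21 acute phase genes 4 rose (6 adjusted over the list alone; camera adjusted p = 1.16e-06, and 0.49 with an estimated correlation). Of 23 ribosome biogenesis and Myc response genes 4 rose (10 adjusted over the list alone; camera adjusted p = 9.22e-06, and 0.502 with an estimated correlation). Neutrophil markers moved with these groups: 5 of 11 rose (9 adjusted over the list alone), with S100a8 higher by 3.88 (SE 0.91) and S100a9 by 3.40 (SE 0.78), at camera adjusted p = 1.29e-05 and 0.478 with an estimated correlation. Ccnd1 (log2 change -0.04, SE 0.45), Cdk1 (-1.02, SE 0.77) and Cdkn1a (2.91, SE 0.99, adjusted p = 0.0647) did not pass. Cdkn1a passed by DESeq2, without the count filter, without the 6 h sham livers and without WT sham replicate 5. The count was 419, 807, 786, 764 and 2704 without WT sham replicates 1 to 5 in turn, and 607, 805 and 55 without WT 6 h replicates 1 to 3. Il1rn, Atf3 and Ier3 passed whichever library was left out, and the other rising and falling genes named here lost their call without WT 6 h replicate 3. Fitting the 2 groups alone called 1 gene and male libraries alone 18, none of them a gene named here. The count was 2010 without the sex term, 2041 without the count filter and 1971 without the 6 h sham livers.

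The KO response at 6 h (n = 3, against 5 sham livers) changed 1030 genes, 640 higher and 390 lower, and 880 by at least 2-fold. Gdf15, a stress-induced cytokine, rose by 5.44 (SE 0.79, adjusted p = 0.000165), Hilpda by 5.32 (SE 0.94) and the lipid droplet coat gene Plin2 by 2.79 (SE 0.56). Immediate early genes rose in 17 of 20 cases, among them Egr1 by 4.45 (SE 0.79), Atf3 by 4.23 (SE 0.64) and Klf6 by 2.71 (SE 0.47). All 20 passed adjusted over the list alone, and camera gave adjusted p = 1.43e-17, and 0.313 with an estimated correlation. Of 19 TGFβ pathway genes 7 rose (7 adjusted over the list alone), including the ligand gene Tgfb3 by 2.66 (SE 0.48) and the TGFβ target Pmepa1 by 1.76 (SE 0.42), with camera adjusted p = 2.45e-05, and 0.324 with an estimated correlation. Of 14 inflammatory cytokine and NF-κB genes, 6 rose (9 adjusted over the list alone). Camera gave adjusted p = 1.13e-05, and 0.37 with an estimated correlation. No G2/M gene of 30 or S-phase gene of 34 passed edgeR's test, with list medians of -1.68 and -0.655. Camera ranked both lists downward at adjusted p = 0.000364 and 0.0147, and 0.879 for both with an estimated correlation. Fam13a fell by 3.76 (SE 0.82) on the log2 scale. Lipid droplet genes rose in 3 of 17 cases (5 adjusted over the list alone; camera adjusted p = 0.000187, and 0.37 with an estimated correlation). The genes named so far for the KO at 6 h passed whichever single library was left out, but Tgfb3 lost its call in a fit of the 2 groups alone and Fam13a in males alone. Ccnd1 rose by 1.40 (SE 0.43, adjusted p = 0.0456) and Cdkn1a by 3.28 (SE 1.0, adjusted p = 0.0456), and both lost their calls in a fit of the 2 groups alone, in males alone and without any of KO sham replicates 1 to 4 or KO 6 h replicates 1 to 3. Ccnd1 also lost its call with RLE scaling and without the sex term. The count was 608 without KO sham replicate 1 and 288 and 532 without KO 6 h replicates 1 and 3. It was 264 in a fit of the 2 groups alone, 380 in males alone, 1606 by DESeq2, 1855 without the count filter and 1704 without the 6 h sham livers.

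WT and KO livers shared much of the 6 h response, measured against separate sham libraries. Of the genes that changed at 6 h, 331 rose in both genotypes against 26.6 expected from independent lists, and 147 fell in both against 14.4 expected. All 478 shared genes had the same direction.

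At 24 h the WT liver showed lower expression of metabolic genes. Against sham (n = 5), 144 genes changed at 24 h (n = 3), 57 higher and 87 lower, and 131 by at least 2-fold. Thrsp, a regulator of lipogenesis, changed by -4.10 on the log2 scale (SE 0.76, adjusted p = 0.0127). The acetyl-CoA carboxylase genes Acacb and Acaca changed by -2.28 (SE 0.33) and -1.85 (SE 0.35), the liver pyruvate kinase gene Pklr by -2.43 (SE 0.49) and Aacs by -2.55 (SE 0.51). The hepcidin gene Hamp2, whose close paralog makes its value uncertain, changed by -4.99 (SE 0.95), and the glutaminase gene Gls2 by -1.30 (SE 0.22). Tpm1, a tropomyosin gene, rose by 1.89 (SE 0.31). Of 19 lipogenesis genes 8 fell (15 adjusted over the list alone), a call that held with camera's estimated correlation (adjusted p = 0.0128). Of 11 periportal genes 1 fell (6 adjusted over the list alone; adjusted p = 0.0165 with an estimated correlation). Of 20 cytochrome P450 and xenobiotic genes 3 fell (11 adjusted over the list alone; camera adjusted p = 7.75e-12, and 0.0815 with an estimated correlation). Of 24 bile acid genes 2 fell, the sterol hydroxylase gene Cyp27a1 at -1.48 (SE 0.28) and the bile acid ligase gene Slc27a5 at -1.48 (SE 0.30) (3 adjusted over the list alone; camera adjusted p = 1.55e-05, and 0.101 with an estimated correlation). No S-phase gene of 34 passed edgeR's test (13 at an unadjusted p under 0.05, 0 by DESeq2 or adjusted over the list alone). The list's median was 0.95 with camera adjusted p = 8.01e-05, which was 0.717 with an estimated correlation and 0.439 in the other direction without WT 24 h replicate 2, whose S-phase score was 3.68.

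WT 24 h replicate 3 differed in library makeup, with 8.93% mitochondrial counts and a TMM factor of 1.31. Without it no gene passed edgeR's test (1026 at an unadjusted p under 0.05; DESeq2 was run on all libraries, with 490 genes), so that each gene named for the WT at 24 h lost its call. The count was 318 and 508 without WT 24 h replicates 1 and 2 and 50, 33 and 35 without WT sham replicates 1, 2 and 4. Other settings gave 76 without the sex term, 55 in males alone, 222 with GC and length correction, 1187 without the count filter, 4 without the 6 h sham livers and 0 in a fit of the 2 groups alone (1145 at an unadjusted p under 0.05). In males alone Acaca, Aacs, Gls2, Cyp27a1 and Slc27a5 lost their calls, without the sex term Hamp2 did, and without the 6 h sham livers all genes named but Acacb and Gls2 did.

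More genes passed in the KO at 24 h than in the WT, in separate tests with unequal numbers of libraries. The interaction, which tests the difference of the responses, called 1319 genes but none by edgeR without WT 24 h replicate 3 (3282 at an unadjusted p under 0.05; 2099 by DESeq2 on all libraries), and 3 of the 35 splits run, the real one included, called as many. Against sham (n = 5), 4351 genes changed at 24 h (n = 4), 2477 higher and 1874 lower, and 2832 by at least 2-fold. Cdkn1a, the cell cycle inhibitor p21, rose by 4.86 (SE 1.0, adjusted p = 0.00112), the sphingosine kinase gene Sphk1 by 5.48 (SE 0.80), the phosphatase gene Dusp5 by 5.08 (SE 0.71), the matrix protein gene Npnt by 5.94 (SE 1.0), and the estrogen sulfotransferase gene Sult1e1 by 7.85 (SE 1.3). Acot5, an acyl-CoA thioesterase gene with close paralogs, also rose, from at most 0.03 CPM in the sham livers to 0.18, 44.7, 112 and 171 CPM. Genes that fell included the aldo-keto reductase gene Akr1c14 at -4.05 (SE 0.79), the circadian output factor Dbp at -3.91 (SE 0.86), Hsd3b2 at -3.81 (SE 0.73), Keg1 at -3.75 (SE 0.84), Chac2 at -3.67 (SE 0.62) and the receptor subunit gene Chrna4 at -4.06 (SE 1.0). Each passed whichever single library was left out, but Dbp and Chrna4 lost their calls in males alone.

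Growth-associated and early genes rose together in these KO livers while several non-parenchymal markers fell. Of 23 ribosome biogenesis and Myc response genes 16 rose (18 adjusted over the list alone), including the polyamine enzyme Odc1 by 2.08 (SE 0.34), Gar1 by 1.93 (SE 0.33) and Ddx21 by 1.55 (SE 0.30). Of 20 immediate early genes 16 rose (18 adjusted over the list alone), including Egr1 by 3.74 (SE 0.73). By camera the lists had adjusted p = 6.22e-08 and 2.98e-07, and 0.785 for both with an estimated correlation. Lipogenesis genes fell in 11 of 19 cases (13 adjusted over the list alone; camera adjusted p = 4.21e-07, and 0.755 with an estimated correlation), with Acacb at -3.12 (SE 0.31) and the fatty acid elongase gene Elovl6 at -3.39 (SE 0.48). Cholesterol synthesis genes fell in 8 of 21 cases (8 adjusted over the list alone; camera adjusted p = 4.76e-05, and 0.785 with an estimated correlation). Markers of Kupffer cells, the resident macrophages, fell in 10 of 12 cases (10 adjusted over the list alone), those of T and NK cells in 8 of 15 (12) and those of sinusoidal endothelial cells in 8 of 14, with 1 higher (10 lower and 1 higher adjusted over the list alone). Examples were Clec4f at -1.67 (SE 0.38), the granzyme gene Gzmb at -3.27 (SE 0.65) and the endothelial lectin gene Clec4g at -1.95 (SE 0.38). The camera test gave adjusted p = 0.000214, 1.1e-05 and 0.00107 for the 3 marker lists, and 0.785 for each with an estimated correlation. The genes named here passed whichever single library was left out. The count was 2526 without KO 24 h replicate 4 and 1028 in a fit of the 2 groups alone. Replicate 1 of this group scored -26.8 on the first principal component and the other replicates 90.6, 122 and 98.0. At 24 h, 51 genes changed in both genotypes, 19 higher in both against 9.07 expected from independent lists and 29 lower in both against 10.5 expected.

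At 48 h cell cycle genes were higher in the WT livers as a group, but not in replicate 3. Its S-phase and G2/M scores (1.93 and 0.425) lay below the WT sham means (2.13 and 0.777). Against sham (n = 5), 1291 genes changed at 48 h (n = 4), 728 higher and 563 lower, and 968 by at least 2-fold. Of 30 G2/M genes 29 rose (30 adjusted over the list alone), among them the mitotic kinase Cdk1 by 3.58 (SE 0.66, adjusted p = 0.00131) and the kinase gene Aurka by 3.75 (SE 0.74). Of 34 S-phase genes 19 rose (31 adjusted over the list alone), such as Gins2 by 2.67 (SE 0.61) and Fen1 by 1.54 (SE 0.36). Camera gave adjusted p = 6.52e-18 and 2.9e-11, and 0.187 and 0.249 with an estimated correlation. Mki67, a proliferation marker, rose by 4.09 (SE 0.93), and Afp, the fetal serum protein alpha-fetoprotein, by 4.16 (SE 0.56), the cytokinesis factor Ect2 by 4.12 (SE 0.80), the serine synthesis enzyme Psat1 by 4.10 (SE 0.62), Loxl4 by 4.07 (SE 0.78) and Ccdc120 by 3.85 (SE 0.43). Cdk1, Aurka, Gins2, Fen1 and Mki67 lost their calls in a fit of the 2 groups alone, and Gins2, Fen1 and Mki67 without the 6 h sham livers.

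Metabolic genes fell in the same livers. The log2 change was -5.29 for Thrsp (SE 0.71), -6.95 for Hamp2 (SE 0.93), -5.45 for Rgs16 (SE 0.95), -3.75 for Upp2 (SE 0.76), -3.67 for Cyp2a5 (SE 0.77) and -3.12 for Inmt (SE 0.77). Hamp2 and Cyp2a5 have close paralogs. Of 19 lipogenesis genes 11 fell (15 adjusted over the list alone) and of 19 urea cycle and amino acid catabolism genes 11 fell (11), including the proline dehydrogenase gene Prodh at -2.10 (SE 0.36) and Gls2 at -1.45 (SE 0.20). Both calls, and that of the periportal genes (6 lower and 1 higher of 11, also adjusted over the list alone), held with an estimated correlation at adjusted p = 0.0432. P450 genes fell in 7 of 20 cases (11 adjusted over the list alone; camera adjusted p = 6.96e-09, and 0.088 with an estimated correlation), including Cyp2e1 at -1.82 (SE 0.36). Antigen-presentation markers fell in 5 of 9 cases (7 adjusted over the list alone; camera adjusted p = 1.71e-05, and 0.0527 with an estimated correlation), among them Cd74 at -2.21 (SE 0.46). T and NK cell markers fell in 3 of 15 (14 adjusted over the list alone; camera adjusted p = 9.99e-09, and 0.088 with an estimated correlation). No single library moved the count beyond 1.5 times (880 to 1292), and the genes named passed in each of those fits. The count was 377 in a fit of the 2 groups alone, 301 in males alone, 2075 without the count filter and 588 without the 6 h sham livers. Upp2, Cyp2a5 and Inmt lost their calls in the fit of the 2 groups alone and in males alone, Inmt also without the 6 h sham livers, and Gls2 and Cyp2e1 in males alone.

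The KO liver at 48 h also showed a rise in cell cycle genes. Against sham (n = 5), 467 genes changed at 48 h (n = 4), 358 higher and 109 lower, and 394 by at least 2-fold; DESeq2 called 458 higher and 231 lower, and GC and length correction 402 and 232. Of 34 S-phase genes 26 rose (34 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.0368), including the helicase subunit Mcm5 by 4.01 (SE 0.72, adjusted p = 0.00191), the licensing factor Cdc6 by 4.43 (SE 0.91), Chaf1a by 3.42 (SE 0.58) and Fen1 by 2.26 (SE 0.36). Of 30 G2/M genes 24 rose (30 adjusted over the list alone; camera adjusted p = 9.91e-38, and 0.0796 with an estimated correlation), with Cdk1 higher by 3.49 (SE 0.63) and Foxm1 by 3.73 (SE 0.75). Uhrf1, a factor of maintenance DNA methylation, rose by 4.44 (SE 0.92), Birc5 by 3.94 (SE 0.81), Lockd by 4.31 (SE 0.86) and the G1 cyclin gene Ccnd1 by 2.16 (SE 0.41). Of 19 lipogenesis genes 7 fell (12 adjusted over the list alone; adjusted p = 0.0368 with an estimated correlation), including Acacb at -2.49 (SE 0.30), Pklr at -2.49 (SE 0.44) and Elovl6 at -2.45 (SE 0.46). Outside the list, the fatty acid binding protein gene Fabp5 stood at -2.61 (SE 0.50) and Rgs16 at -4.32 (SE 0.89). These genes passed whichever single library was left out, but Ccnd1 lost its call without the sex term. The count was 304, 277 and 280 without KO sham replicates 1, 3 and 5 and 210, 302 and 266 without KO 48 h replicates 1 to 3. It was 262 in males alone, 828 without the count filter and 275 without the 6 h sham livers. At 48 h, 299 genes changed in both genotypes, all in the same direction. Of these, 234 rose in both against 16.7 expected from independent lists and 65 fell in both against 3.94 expected.

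**Figure D3:**
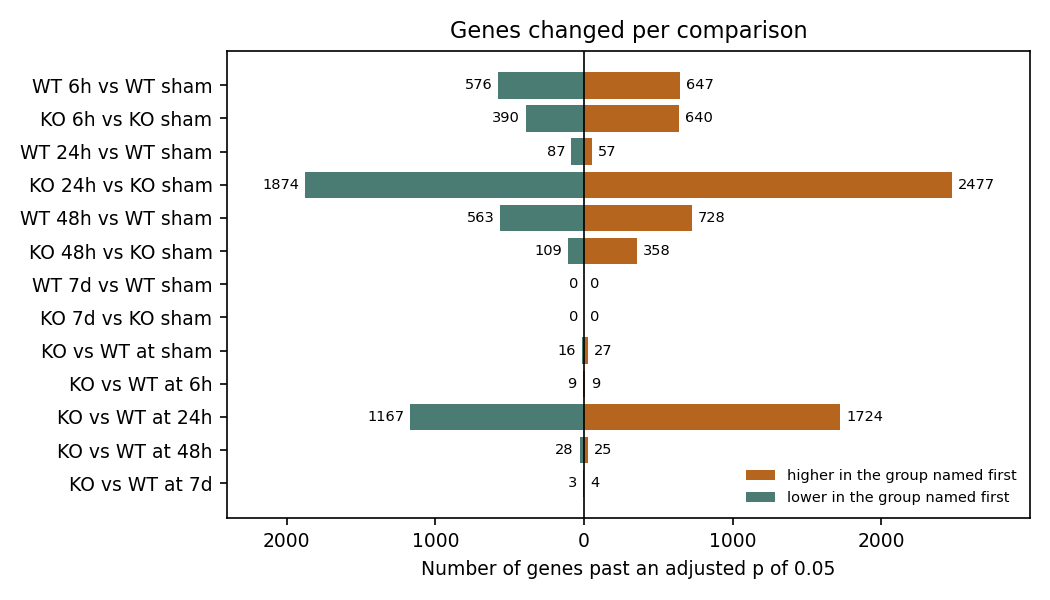
Number of genes past the adjusted threshold (horizontal axis) for each of 13 comparisons (vertical axis), with genes higher in the first group to the right and lower to the left. The KO 24 h response (2477 higher, 1874 lower) and the KO to WT comparison at 24 h (1724 higher, 1167 lower) have the longest bars.

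By 7 d after hepatectomy no gene passed edgeR's test against sham in either genotype (n = 3 and 5 in each). In the WT, 950 genes had an unadjusted p under 0.05 and DESeq2 called 25; in the KO the numbers were 497 and 8. Ccnd1 was at a log2 change of 0.81 (SE 0.43, adjusted p = 0.836) in the WT and 1.55 (SE 0.43, adjusted p = 0.978) in the KO. No S-phase gene of 34 passed edgeR's test in the KO (10 at an unadjusted p under 0.05, 0 by DESeq2), with a list median of 0.71 and camera adjusted p = 5.89e-13, which was 0.634 with an estimated correlation. In the WT no sinusoidal endothelial marker of 14 passed (1 lower adjusted over the list alone, 10 lower at an unadjusted p under 0.05, 0 by DESeq2), with a median of -0.82 and camera adjusted p = 2.89e-09, which was 0.552 with an estimated correlation. The WT count was 2 without WT 7 d replicate 1 and 2 without replicate 2, and 250 without the count filter. In the KO it was 155 without the count filter, 3 in a fit of the 2 groups alone and 2 with GC and length correction.

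Sham livers of the genotypes (n = 5 each) differed in few genes. In the KO 27 genes were higher and 16 lower than in the WT, 43 in all, 42 of them by at least 2-fold; DESeq2 called 212 higher and 60 lower. Hddc3, a gene for a nucleotide pyrophosphohydrolase (ENSMUSG00000030532, chromosome 7, 80343104 to 80350547), was higher in the KO by 3.01 (SE 0.34, adjusted p = 1.87e-06). Wdfy1, an endosomal protein gene (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143), was lower by -2.51 (SE 0.27, adjusted p = 1.11e-06), Nnt, the mitochondrial transhydrogenase gene (the identifier ENSMUSG00000116207 of 2 that overlap), by -1.47 (SE 0.22) and Lrrc32 by -1.35 (SE 0.24). Hddc3 and Lrrc32 lie within 20 Mb of Nox4 on chromosome 7. Over all stages Hddc3 stood at 8.62 ± 3.97 CPM in the KO (SD, n = 19) and 1.06 ± 0.551 CPM in the WT (SD, n = 18), and Wdfy1 at 4.70 ± 1.94 and 21.0 ± 2.72 CPM, each with no overlap between the genotypes. These genes were singled out for this after their values were seen, and chance gives a separation as complete in 1.13e-08 percent of groupings.

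No mitochondrially encoded gene of 13 passed edgeR's test between sham livers (5 higher adjusted over the list alone, 6 at an unadjusted p under 0.05, 4 by DESeq2). The median was 0.54 with camera adjusted p = 0.000214, which was 0.938 with an estimated correlation and 0.000137 in the other direction with GC and length correction. No gene of the S-phase (34 tested), G2/M (30), TGFβ (19), bile acid (24), fatty acid oxidation (22) or lipogenesis (19) lists passed edgeR's test between sham livers, in all genes or adjusted over the list alone; 0, 0, 4, 0, 1 and 3 had an unadjusted p under 0.05, and DESeq2 called 0. Of 8 cholangiocyte markers 1 was lower in the KO, Krt19 at -2.31 (SE 0.50) (4 lower adjusted over the list alone; camera adjusted p = 0.00177, and 0.938 with an estimated correlation; 0.0691 without WT sham replicate 1). Krt19 lost its call without WT sham replicates 1 or 2 or KO sham replicates 2 to 5, in a fit of the 2 groups alone, in males alone, with GC and length correction and without the 6 h sham livers. In the other 13 cell type lists no marker passed edgeR's test, with at most 4 at an unadjusted p under 0.05 and at most 1 by DESeq2. Adjusted over the list alone, 2 sinusoidal endothelial, 1 erythroid and 3 mesothelial markers were lower and none passed in the other lists. Hddc3, Wdfy1, the named Nnt and Lrrc32 passed whichever single library was left out, but all save Wdfy1 lost their calls in males alone, and Lrrc32 also in a fit of the 2 groups alone and with GC and length correction. The count was 21, 28 and 77 without WT sham replicates 1, 2 and 5 and 65 and 25 without KO sham replicates 2 and 3. It was 3 in males alone, 21 in a fit of the 2 groups alone, 28 with GC and length correction, 18 without the 6 h sham livers and 871 without the count filter.

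At 6 h after hepatectomy (n = 3 each) 18 genes differed between the genotypes, 9 higher and 9 lower in the KO, 16 by at least 2-fold. Hddc3 was higher by 4.32 (SE 0.49, adjusted p = 9.26e-06) and Aqp11, a water channel gene within 20 Mb of Nox4, by 2.30 (SE 0.35, adjusted p = 0.000989); both passed whichever library was left out, and Aqp11 lost its call in a fit of the 2 groups alone. Wdfy1 was lower by -2.07 (SE 0.35, adjusted p = 0.00333) and lost its call without KO 6 h replicate 1. No gene of the S-phase, G2/M, TGFβ, bile acid, fatty acid oxidation or lipogenesis lists passed edgeR's test (1, 0, 1, 2, 4 and 2 at an unadjusted p under 0.05; by DESeq2 1 in fatty acid oxidation and 0 in the others). Adjusted over the list alone, 4 fatty acid oxidation genes were higher and none passed in the others. By camera the unfolded protein response and acute phase lists were lower in the KO and the NRF2 antioxidant list higher (adjusted p = 0.013 each). The cholesterol synthesis (adjusted p = 0.0184), fatty acid oxidation and lipid droplet lists (0.0225 each) were also higher by camera. With an estimated correlation each of these lists had adjusted p = 0.91, and none of their genes passed over all genes. No marker of 14 cell type lists passed, 1 mesothelial marker was higher adjusted over the list alone, with at most 2 per list at an unadjusted p under 0.05 and at most 1 by DESeq2. The count was 11, 9 and 7 without WT 6 h replicates 1 to 3 and 6, 236 and 7 without KO 6 h replicates 1 to 3. It was 5 in a fit of the 2 groups alone, 6 in males alone, 127 by DESeq2 and 358 without the count filter. The difference of the responses, tested as an interaction, called no gene by edgeR (715 at an unadjusted p under 0.05, 9 by DESeq2). By edgeR it called 4 without KO 6 h replicate 2 and 110 without the count filter. In this interaction camera ranked the mesothelial list upward (adjusted p = 6.2e-07). The unfolded protein response and acute phase lists ranked downward (camera adjusted p = 9.09e-05 each). With an estimated correlation the adjusted p-values were 0.304, 0.891 and 0.974.

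Of the comparisons between the genotypes at each stage, that at 24 h had the most genes called. Chance was not excluded for this count, since 3 of 35 splits of the libraries, the real one included, called as many. The highest other split called 5860 genes, and KO 24 h replicate 1 lay near WT livers on the first principal component (-26.8). In the KO (n = 4) against the WT (n = 3), 1724 genes were higher and 1167 lower, 2891 in all, with 1195 higher and 939 lower by at least 2-fold. Genes of the glutathione and xenobiotic defence were among them. The sulfiredoxin gene Srxn1 was higher by 3.23 (SE 0.62, adjusted p = 0.00175) and the glutathione transferase gene Gsta1, which has a close paralog, by 6.43 (SE 1.5). Slc7a11, the cystine transporter gene, was also called higher, at 0.04, 16.7, 10.7 and 0.59 CPM in KO replicates 1 to 4 against at most 0.03 CPM in the WT. Cd14, the endotoxin co-receptor gene, was higher by 6.40 (SE 1.2), Npnt by 6.13 (SE 1.3) and the bile acid exporter subunit gene Slc51b by 5.91 (SE 1.4). Acot5 was called higher as well, with 0 CPM in each WT 24 h library. Akr1c14 was lower by -3.63 (SE 0.82), Chac2 by -3.35 (SE 0.66), Hsd3b2 by -3.24 (SE 0.76) and the growth factor receptor gene Kit by -2.86 (SE 0.63).

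Of 20 NRF2 antioxidant genes 10 were higher and 1 lower in the KO (12 and 1 adjusted over the list alone), with the reductase genes Gsr at 1.23 (SE 0.27) and Txnrd1 at 1.32 (SE 0.30). Ribosome biogenesis and Myc response genes were higher in 17 of 23 cases (22 adjusted over the list alone), including Gar1 at 2.42 (SE 0.40) and Ddx21 at 1.86 (SE 0.36), and immediate early genes in 12 of 20 (15), including Myc at 3.32 (SE 0.72) and Klf6 at 2.39 (SE 0.53). Camera gave adjusted p = 0.000113, 2.32e-10 and 4.69e-06, and adjusted p = 0.923 for each with an estimated correlation. Sinusoidal endothelial markers were lower in 10 of 14 cases (12 lower and 1 higher adjusted over the list alone), including Clec4g at -2.51 (SE 0.42) and the receptor gene Kdr at -2.30 (SE 0.56), and Kupffer cell markers in 3 of 12 (7). For these markers camera gave adjusted p = 3.37e-05 and 0.00134, and 0.923 with an estimated correlation. Of 21 cholesterol synthesis genes 4 were lower (7 adjusted over the list alone; camera adjusted p = 0.000885, 0.923 with an estimated correlation, and 0.0722 without WT 24 h replicate 1). Of 13 mitochondrially encoded genes 2 were higher (2 adjusted over the list alone; camera adjusted p = 0.00297, and 0.923 with an estimated correlation). These were mt-Nd1 at 1.14 (SE 0.30, adjusted p = 0.0108) and mt-Nd4 at 0.84 (SE 0.28, adjusted p = 0.0351). Both lost their calls in a fit of the 2 groups alone and without WT 24 h replicate 1 or KO 24 h replicate 3. The call of mt-Nd4 was also lost without WT 24 h replicate 2 or KO 24 h replicate 4, without the count filter or the sex term, in males alone and with GC and length correction.

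Of 34 S-phase genes at 24 h, 7 were lower in the KO and 1 higher (14 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0163, which was 0.923 with an estimated correlation, 0.0622 without KO 24 h replicate 2 and 0.724 in the other direction without WT 24 h replicate 2. The S-phase genes Gins1 at -1.43 (SE 0.37) and Tk1 at -2.39 (SE 0.66) lost their calls without WT 24 h replicate 2, and Tk1 also without KO 24 h replicate 4. No G2/M gene of 30 passed edgeR's test, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by DESeq2). Of 19 TGFβ genes 4 were higher and 1 lower (the same adjusted over the list alone), including the receptor gene Tgfbr2 at 2.53 (SE 0.54) and Tgif1 at 2.27 (SE 0.50). Camera gave adjusted p = 0.049, which was 0.923 with an estimated correlation, 0.0527 without the sex term and 0.206, 0.0556, 0.138 and 0.106 without WT 24 h replicates 1 and 3 and KO 24 h replicates 2 and 3. Bile acid genes were 1 higher and 2 lower of 24, fatty acid oxidation genes 1 higher of 22 and lipogenesis genes 1 higher and 2 lower of 19, with equal counts adjusted over the list alone. Thrsp was higher by 3.56 (SE 0.74) and the peroxisomal thiolase gene Acaa1b by 2.05 (SE 0.46).

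Of the other cell type lists at 24 h, cholangiocyte markers were 2 higher of 8, and adipocyte (6 tested), monocyte (12), stellate cell (14) and T and NK cell (15) markers each had 1 lower, with 1 of 8 erythroid markers higher. Adjusted over the list alone these counts were 2 higher, 1 lower, 1 lower, 2 higher and 2 lower, none, and 1 higher. No neutrophil, B cell, antigen-presentation, platelet or mesothelial marker passed edgeR's test (0, 1, 0, 0 and 0 at an unadjusted p under 0.05, 0 by DESeq2). Skeletal muscle markers were lower in the KO in 4 of 11 cases (11 adjusted over the list alone), with a median of -6.38 and camera adjusted p = 0.187; the muscle genes Srl at -5.51 (SE 1.2) and Eno3 at -3.39 (SE 0.68) lost their calls without WT 24 h replicate 3.

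Apart from Gins1, Tk1, Srl, Eno3, mt-Nd1 and mt-Nd4, the genes named for this comparison passed whichever single library was left out. The count was 1789 without WT 24 h replicate 1 and 5452, 1894, 1366 and 998 without KO 24 h replicates 1 to 4. Male libraries alone gave 1245 higher and 1219 lower, and a fit without the count filter 1518 and 1924. A fit of the 2 groups alone called no gene by edgeR (2157 at an unadjusted p under 0.05, and 3489 by DESeq2 on all libraries).

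The response to hepatectomy differed between the genotypes at 24 h for 1319 genes by the interaction test, 859 higher and 460 lower in the KO than the WT response, 1210 by at least 2-fold (1181 higher and 382 lower with GC and length correction). Runx1, a transcription factor gene, differed by 6.80 (SE 1.3, adjusted p = 0.00841), the amino acid transporter gene Slc7a6 by 6.43 (SE 1.2), Cd14 by 6.02 (SE 1.3), Chac2 by -5.10 (SE 0.84), Akr1c14 by -4.85 (SE 1.0) and Tasor by -4.17 (SE 0.88). Of 23 ribosome biogenesis and Myc response genes 11 had a higher KO response (18 adjusted over the list alone; camera adjusted p = 5.62e-10, and 0.913 with an estimated correlation), including Heatr1 at 2.20 (SE 0.50) and Pes1 at 1.29 (SE 0.28). Without WT 24 h replicate 3 no gene passed (3282 at an unadjusted p under 0.05; DESeq2 called 2099 on all libraries), so each of these genes lost its call. The count was 756, 638 and 867 without WT sham replicate 5, KO sham replicate 3 and KO sham replicate 4, and 3659, 617 and 471 without KO 24 h replicates 1, 3 and 4. It was 2361 without the count filter, 709 without the 6 h sham livers and 0 in a fit of the 4 groups alone (3082 at an unadjusted p under 0.05).

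At 48 h (n = 4 each) the genotypes differed in 53 genes, 25 higher and 28 lower in the KO, 52 by at least 2-fold. Hddc3 was higher by 2.85 (SE 0.39, adjusted p = 7.05e-05), and Plekhb1, within 20 Mb of Nox4, by 2.17 (SE 0.31). Afp was lower by -3.42 (SE 0.62, adjusted p = 0.00509), the thymidine phosphorylase gene Tymp by -2.11 (SE 0.29) and Wdfy1 by -2.33 (SE 0.30). These genes passed whichever single library was left out, but Plekhb1, Afp and Tymp lost their calls in males alone and Afp in a fit of the 2 groups alone. Thrsp (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730, within 20 Mb of Nox4) was higher by 3.38 (SE 0.66, adjusted p = 0.0106) and lost its call without WT 48 h replicate 3 and in males alone. The core clock gene Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126) was lower by -3.38 (SE 0.69, adjusted p = 0.0151) and lost its call without any of KO 48 h replicates 1 to 3 and in males alone. Of 18 circadian clock genes 1 was higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.00239, and 0.305 with an estimated correlation).

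Cell cycle genes did not pass between the genotypes at 48 h. No S-phase gene of 34 passed edgeR's test, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by DESeq2), with a list median of 0.55 and camera adjusted p = 1.62e-07, which was 0.744 with an estimated correlation. No G2/M gene of 30 passed edgeR's test either way (0 at an unadjusted p under 0.05, 0 by DESeq2), with a median of 0.02 and camera adjusted p = 0.000732, which was 0.808 with an estimated correlation and 0.278 in the other direction without WT 48 h replicate 3. Cdk1 differed by 0.14 (SE 0.62), Mki67 by -0.01 (SE 0.83) and Ccnd1 by 0.21 (SE 0.43). The S-phase score, the mean log2(CPM + 1) of the list, was 3.77 ± 0.387 in the KO and 3.10 ± 0.906 in the WT (SD, n = 4 each; difference 0.665, two-sided exact permutation p = 0.229, adjusted p = 0.382). It stood at 3.29, 3.06, 1.93 and 4.12 in WT 48 h replicates 1 to 4, so much of this difference came from replicate 3. The G2/M score was 3.34 ± 0.393 and 2.78 ± 1.76 (difference 0.553, n = 4 each, exact permutation p = 0.686, adjusted p = 0.9). It stood at 3.90, 2.47, 0.425 and 4.34 in WT 48 h replicates 1 to 4, so the sign of the difference rested on replicate 3. Neither score passed at any other stage, with p adjusted over the 5 stages of each score from 0.382 to 0.9. These tests had little power, since 3 against 3 libraries, as at 6 h and 7 d, cannot give a p below 0.1, and those at 24 h and 48 h cannot give one below 0.0286 before adjustment.

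**Figure D4:**
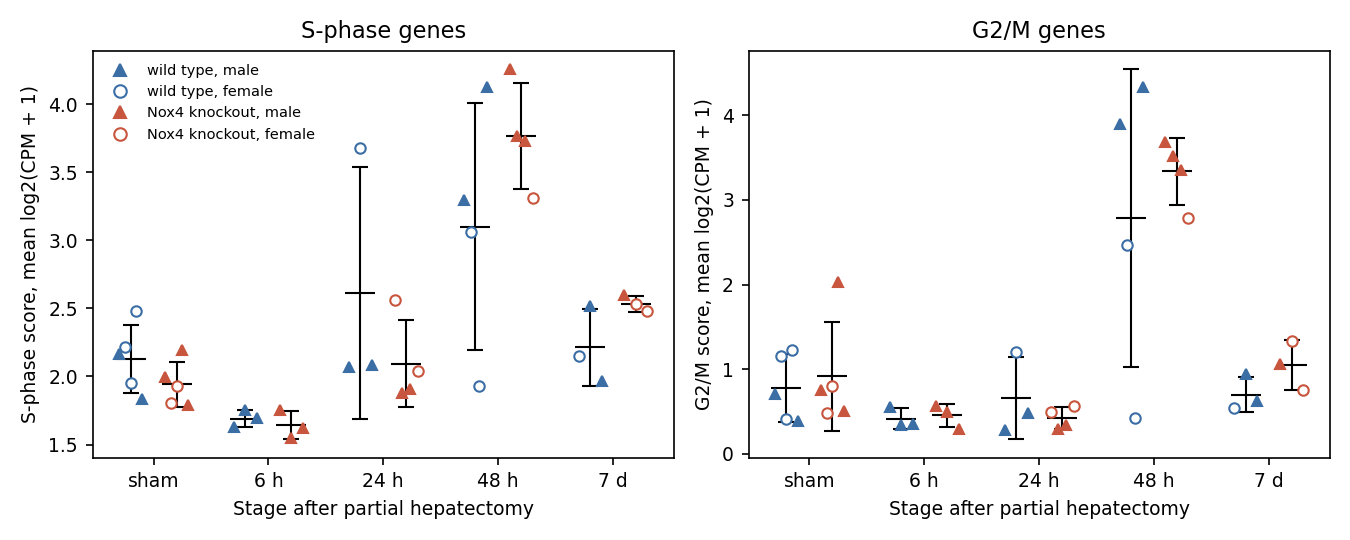
S-phase score (one panel) and G2/M score (the other panel), each the mean log2(CPM + 1) of its list (vertical axes), for every library by stage (horizontal axes), WT in blue and KO in red, triangles for males and open circles for females; bars give the mean ± SD of each group. At 48 h the S-phase score was 3.77 ± 0.387 in the KO and 3.10 ± 0.906 in the WT (n = 4 each).

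Of 20 NRF2 genes at 48 h none passed edgeR's test (7 higher adjusted over the list alone, 8 at an unadjusted p under 0.05, 3 by DESeq2), with camera adjusted p = 5.69e-06, which was 0.419 with an estimated correlation. T and NK cell markers were 1 higher of 15 (5 adjusted over the list alone; camera adjusted p = 1.45e-06, and 0.419 with an estimated correlation), the granzyme gene Gzmb at 2.63 (SE 0.61), which lost its call without WT 48 h replicates 1, 2 or 3 or KO 48 h replicates 1, 3 or 4, without the sex term, in males alone and with GC and length correction. Lipogenesis genes were 1 higher of 19, Thrsp. No TGFβ, bile acid or fatty acid oxidation gene passed (3, 8 and 5 at an unadjusted p under 0.05; 0, 1 and 0 by DESeq2; 0, 1 and 0 adjusted over the list alone), nor any marker of the other 13 cell type lists (at most 4 at an unadjusted p under 0.05 and 0 by DESeq2; adjusted over the list alone, 1 B cell and 2 antigen-presentation markers were higher). The count was 25 and 139 without WT 48 h replicates 3 and 4 and 30, 29, 30 and 30 without KO 48 h replicates 1 to 4. It was 27 in a fit of the 2 groups alone, 17 in males alone, 226 by DESeq2 and 621 without the count filter. The interaction at 48 h called no gene by edgeR (1198 at an unadjusted p under 0.05, 50 by DESeq2), and 30, 1, 20 and 1 without WT sham replicate 5, WT 48 h replicates 2 and 4 and KO sham replicate 5. It called 12 without the 6 h sham livers and 401 without the count filter. The G2/M list had a median of -0.38 there while camera ranked it upward (adjusted p = 0.0217, and 0.852 with an estimated correlation).

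At 7 d (n = 3 each) 7 genes differed, 4 higher and 3 lower in the KO. Wdfy1 was lower by -2.41 (SE 0.35, adjusted p = 0.0005), whichever library was left out, and Hddc3 was higher by 2.88 (SE 0.44, adjusted p = 0.000966) but lost its call without WT 7 d replicate 1. It also lost its call in males alone, a fit with only 1 KO male and 2 WT males at 7 d, which says little. No NRF2 gene of 20 passed edgeR's test (2 higher adjusted over the list alone, 5 at an unadjusted p under 0.05, 1 by DESeq2), with a median of 0.62 and camera adjusted p = 2.13e-09, which was 0.474 with an estimated correlation. No gene of the S-phase, G2/M, TGFβ, bile acid, fatty acid oxidation or lipogenesis lists passed (0, 0, 0, 1, 3 and 1 at an unadjusted p under 0.05; by DESeq2 1 in bile acid and 0 in the others; adjusted over the list alone, 1 in bile acid), and no marker of 14 cell type lists did (at most 4 at an unadjusted p under 0.05 and at most 1 by DESeq2). DESeq2 called 30 genes, a fit without the count filter 97 and male libraries alone 2, the last with 1 KO male. The interaction at 7 d called no gene by edgeR (347 at an unadjusted p under 0.05, 3 by DESeq2), and 67 without the count filter.

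Averaged over the stages, 423 genes differed between KO (n = 19) and WT (n = 18), 315 higher and 108 lower in the KO, 169 by at least 2-fold. Of 20 NRF2 antioxidant genes 9 were higher (17 adjusted over the list alone), with a median of 0.63 and camera adjusted p = 6.44e-13, which was 0.149 with an estimated correlation. They included the quinone reductase Nqo1 at 0.89 (SE 0.19, adjusted p = 0.00704), the epoxide hydrolase Ephx1 at 0.64 (SE 0.14), the glutathione synthesis subunit Gclm at 0.48 (SE 0.10) and Gsta1 at 2.54 (SE 0.56). Of the other genes called, some with larger changes not given here, Hddc3 was higher by 3.13 (SE 0.19), Cyp2a22, which has close paralogs, by 3.03 (SE 0.46), Erdr1 by 1.74 (SE 0.20) and Thrsp by 1.61 (SE 0.29). Wdfy1 was lower by -2.19 (SE 0.14), Tymp by -1.46 (SE 0.13) and Nnt (ENSMUSG00000025453) by -1.38 (SE 0.16). These genes passed whichever single library was left out, but Gclm lost its call in males alone and with GC and length correction.

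Among genes with a known position, 43 called genes lay within 20 Mb of Nox4, 17.4% of the 247 tested there against 2.47% of the 15302 tested elsewhere. Aen, a p53 target gene among them, was higher by 0.68 (SE 0.11). No S-phase, G2/M, TGFβ or bile acid gene passed edgeR's test in the averaged comparison (1, 0, 4 and 5 at an unadjusted p under 0.05; 0, 0, 1 and 2 by DESeq2; 2 bile acid genes adjusted over the list alone). The S-phase median was -0.05 while camera ranked the list upward (adjusted p = 0.803, and 0.0261 without WT 24 h replicate 2). Fatty acid oxidation genes were 1 higher of 22 (3 adjusted over the list alone) and lipogenesis genes 2 higher, 1 of them Thrsp, and 1 lower, Acacb at -0.67 (SE 0.14), of 19, a call lost in males alone. Of 13 mitochondrially encoded genes 2 were higher (7 adjusted over the list alone), mt-Co2 at 0.57 (SE 0.15, adjusted p = 0.0384) and mt-Nd6 at 0.70 (SE 0.17, adjusted p = 0.0238). Camera gave adjusted p = 0.000262, which was 0.921 with an estimated correlation and 0.226 in the other direction with GC and length correction. Both genes lost their calls with that correction, in males alone and without WT 24 h replicate 2, WT 7 d replicate 3, KO 48 h replicate 3 or KO 7 d replicates 2 or 3. The call of mt-Co2 was also lost without the 6 h sham livers and without WT sham replicates 1 or 3, WT 6 h replicate 1, WT 24 h replicate 1, WT 48 h replicates 1 or 2, WT 7 d replicates 1 or 2, KO sham replicate 3, KO 6 h replicate 3, KO 24 h replicate 3, KO 48 h replicate 4 or KO 7 d replicate 1. Stellate cell markers were 1 higher and 1 lower of 14, T and NK cell markers 1 higher of 15 and erythroid markers 1 lower of 8, with equal counts adjusted over the list alone. The erythroid marker was Hbb-bt, a gene within 20 Mb of Nox4, at -0.84 (SE 0.23, adjusted p = 0.0447). In the other 11 cell type lists no marker passed edgeR's test, with at most 6 at an unadjusted p under 0.05 and at most 1 by DESeq2. Adjusted over the list alone, 3 cholangiocyte and 4 sinusoidal endothelial markers were lower and 5 antigen-presentation markers higher. The count was 272, 254, 272, 238, 1468 and 202 without WT 6 h replicates 1 and 2, WT 24 h replicates 1, 2 and 3 and WT 7 d replicate 3, and 252, 265, 266, 2029, 254 and 257 without KO sham replicate 3, KO 6 h replicates 1 and 3 and KO 24 h replicates 1, 3 and 4. It was 276, 244 and 225 without KO 7 d replicates 1 to 3, 202 in males alone, 859 by DESeq2 and 1459 without the count filter.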

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

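The tests of GC content, cell share, a 6 h state, strain variants and clock time were chosen after the results were seen, while the other splits of the libraries were planned before.

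Among 82 sets of values checked for 1 library far from the rest of its group, 16 stood out, where chance gives about 1 in 20 groups, or 4.1. WT sham replicate 5, the 6 h sham liver, stood apart in its clock score (-0.676) and in Cdkn1a (132 CPM), Myc (6.21 CPM) and Arntl (5.70 CPM), and KO sham replicate 5, also taken at 6 h, in Cdkn1a (62.8 CPM). KO sham replicate 4 stood apart in its G2/M score (2.03), Mki67 (13.1 CPM) and Cdk1 (4.27 CPM). Thrsp stood at 47.3 CPM in WT 48 h replicate 4 and Myc at 12.1 CPM in KO 48 h replicate 2. Hddc3 stood at 18.7 CPM in KO sham replicate 2 and 16.1 CPM in KO 24 h replicate 1, and Wdfy1 at 6.98 CPM in KO sham replicate 3. The total of KO 24 h replicate 2 was 34728207 counts (34.7 M), the mitochondrial share of KO 48 h replicate 4 was 7.00%, and Nox4 in WT sham replicate 2 was 3.36 CPM, above the other WT females.

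The response to hepatectomy at 24 h differed between the genotypes by the interaction test for 1319 genes. The named genes with a higher KO response were Fosl1 (9.43), Runx1 (6.80), Slc10a6 (6.67), Slc7a6 (6.43), Sult1e1 (6.31) and Cd14 (6.02 on the log2 scale). Those with a lower KO response were A1bg (-5.10), Chac2 (-5.10), Akr1c14 (-4.85), Arhgap5 (-4.26), Pygm (-4.19) and Tasor (-4.17). A1bg also differed by sex (-8.72, males minus females), and the 24 h groups held unequal shares of females. Pygm is the muscle glycogen phosphorylase gene, and the skeletal muscle list had a median of -6.22 in this test. Fosl1 averaged 0.102 and 0.0354 CPM in the WT and KO sham livers, 0.0455 CPM in the WT and 11.5 CPM in the KO at 24 h, so its value stands for presence against near absence and not for a measured fold. Without WT 24 h replicate 3 each of the named genes lost its call and the count was 0.

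For the 2891 genes that differed at 24 h, chance could not be excluded, since 3 of the 35 splits, the real one included, called as many. The highest other split called 5860 genes and set KO 24 h replicate 1 with the WT livers, which points to a structure of the samples. A GC and length correction left 3818 genes, which argues against that bias as the whole cause. Of the 1724 genes called higher in the KO, 1195 were higher by at least 2-fold. That count cannot decide on a lower share of non-parenchymal cells, since small changes were seldom called. In the simulated data 25% of 2-fold changes were recovered in this comparison. Of the 1223 genes of the WT 6 h response, 88.6% lay on the same side in the KO at 24 h relative to the WT, against 26.2% at 48 h and 61.0% at 7 d (60.8% at sham and 23.1% at 6 h, which reuse libraries of that response), so a 6 h-like state of KO livers at 24 h is a candidate explanation. The share moved widely between stages where few genes differed and was not tested against chance, and differences in surgery, fasting or handling were not tested.

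For the 423 genes of the average over stages, chance could not be excluded either, since 2 of the 35 splits, the real one included, called as many, the other with 766. The odds of a call within 20 Mb of Nox4 were 8.32 times those elsewhere (95% interval 5.75 to 11.8, Fisher's exact p = 8.55e-23), so strain variants carried with the targeted locus are a candidate explanation for those calls. Only 43 calls lay there, so variants acting on genes within that window do not account for the rest. This share cannot decide whether linked variants act on distant genes or whether a carried segment is longer than 20 Mb. Variants of a substrain elsewhere in the genome cannot be told apart from an effect of Nox4, since the labels give no strain and the marker genes differ, with 12 and 3 libraries overlapping between the genotypes for the 2 Nnt identifiers and 0 for Wdfy1.

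At 48 h a clock score, the mean of 5 genes of the Arntl phase minus that of 11 genes of the Dbp phase, was lower in the KO by -2.61 (SE 0.63, n = 4 each, two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.143). A difference in the time of day of tissue collection cannot be told apart from a genotype effect, since the labels give no time. In the sham livers the score difference was 0.983 (SE 0.52, n = 5 each). It departed from -2.61, taken as a fixed value (exact permutation p = 0.00794, the smallest possible). This argues against a score difference of that size at every stage. It cannot decide on a constant shift of clock phase, whose effect on the score depends on the unknown time of collection. The difference was -0.49 at 6 h, 1.49 at 24 h and 0.168 at 7 d (exact permutation adjusted p from 0.285 to 0.4).

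In the following comparisons no other split called as many genes as the real one (1 of 35 splits each, the real one included). The 35 were drawn from 56 possible splits for WT 6 h, WT 24 h and KO 6 h and from 126 for WT 48 h, KO 24 h, KO 48 h and the sham livers, and were all those possible at 48 h between the genotypes. The comparisons were WT 6 h (1223 genes, highest other 604), WT 24 h (144 and 1), WT 48 h (1291 and 402), KO 6 h (1030 and 30), KO 24 h (4351 and 2816), KO 48 h (467 and 14), KO against WT sham (43 and 2) and KO against WT at 48 h (53 and 5). A share of 1 of 35 is the smallest that 35 splits can give. It was not adjusted for the number of comparisons, so it does not exclude chance for any of them. For the interaction at 24 h (1319 genes) 3 of 35 splits called as many, the highest 3791, and chance could not be excluded. Where the real count was 0, all 35 splits called as many, with a highest other of 3 for WT 7 d, 1 for KO 7 d and 89, 1 and 5 for the interactions at 6 h, 48 h and 7 d. The splits were too few for KO against WT at 6 h (2 of 10 splits, 18 genes, highest other 121) and 7 d (1 of 10 splits, 7 genes, highest other 0).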

How the results depend on the processing

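The GC and length correction and the fits without the 6 h sham livers were chosen after the data were seen, the other alternatives before. Gene counts are given in the order WT at 6 h, 24 h, 48 h and 7 d, KO at the same times, KO against WT at sham, 6 h, 24 h, 48 h and 7 d, interactions at 6 h, 24 h, 48 h and 7 d, and the average, naming those that moved beyond 1.5 times. By DESeq2 the count was 490 for WT 24 h, 25 for WT 7 d, 1606 for KO 6 h, 8 for KO 7 d, 272, 127, 226 and 30 for KO against WT at sham, 6 h, 48 h and 7 d, 9, 2099, 50 and 3 for the interactions and 859 for the average. RLE scaling moved no count. Without the count filter it was 2041, 1187, 2075 and 250 for the WT, 1855, 828 and 155 for KO 6 h, 48 h and 7 d, 871, 358, 621 and 97 for KO against WT at sham, 6 h, 48 h and 7 d, 110, 2361, 401 and 67 for the interactions and 1459 for the average. Without the sex term it was 2010 for WT 6 h and 76 for WT 24 h. In a fit of the compared groups alone it was 1, 0 and 377 for WT 6 h, 24 h and 48 h, 264, 1028 and 3 for KO 6 h, 24 h and 7 d, 21, 5, 0 and 27 for KO against WT at sham, 6 h, 24 h and 48 h, and 0 for the interaction at 24 h. For these 0 counts by edgeR, 1145, 2157 and 3082 genes had an unadjusted p under 0.05. In male libraries alone it was 18, 55 and 301 for WT 6 h, 24 h and 48 h, 380 and 262 for KO 6 h and 48 h, 3, 6, 17 and 2 for KO against WT at sham, 6 h, 48 h and 7 d (the last with 1 KO male) and 202 for the average. With GC and length correction it was 222 for WT 24 h, 2 for KO 7 d and 28 for KO against WT sham. Without the 6 h sham livers it was 1971, 4 and 588 for WT 6 h, 24 h and 48 h, 1704 and 275 for KO 6 h and 48 h, 18 for KO against WT sham, and 709 and 12 for the interactions at 24 h and 48 h. Leaving out 1 library at a time gave 55 to 2704, 0 to 508, 880 to 1292 and 0 to 2 for the WT, 288 to 1407, 2526 to 6161, 210 to 522 and 0 to 0 for the KO, 21 to 77, 6 to 236, 998 to 5452, 25 to 139 and 5 to 7 for KO against WT, 0 to 4, 0 to 3659, 0 to 30 and 0 to 0 for the interactions and 202 to 2029 for the average. Fits with fewer libraries have less power; beyond that the cause was not tested.

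Of 171 list tests, 138 no longer passed with an estimated correlation. The other 33 kept their side of the threshold, which includes lists that passed with neither correlation. A list's direction reversed in 8 cases, with adjusted p-values as follows. Leaving out 1 library, the lowest to highest value was 2.68e-11 (without WT 24 h replicate 3) to 0.439 for the S-phase list in WT 24 h, 4.03e-13 (without WT 7 d replicate 3) to 0.96 for the acute phase list in WT 7 d, 0.000202 (without WT 24 h replicate 1) to 0.724 for the S-phase list between the genotypes at 24 h and 5.38e-08 (without WT 48 h replicate 4) to 0.278 for the G2/M list between them at 48 h. Without WT 24 h replicate 2 the S-phase list gave 0.439 for WT 24 h and 0.724 for KO against WT at 24 h, without WT 7 d replicate 1 the acute phase list gave 0.96 for WT 7 d, and without WT 48 h replicate 3 the G2/M list gave 0.278 for KO against WT at 48 h. The female-biased list gave 0.832 for KO against WT sham without the sex term. With GC and length correction the mitochondrially encoded genes gave 0.000137 for KO against WT sham, 0.00233 for the interaction at 7 d and 0.226 for the average. The cause was not tested. Of the tests of named genes, leaving out 1 library ended 699 calls, added 180 and left 12115 on their side, and DESeq2 ended 1, added 73 and left 1028. Those left on their side include genes called in neither fit. A fit of the compared groups alone ended 212 calls and added 4, and male libraries alone ended 140 and added 15. Leaving out the 6 h sham livers ended 68 and added 19. No paired analysis was possible because replicate numbers follow the order of deposition and pair no livers. In the simulated data, which had no outlying liver and independent genes, only genes with a mean of at least 1 CPM were changed. There the test recovered 25% of 2-fold changes between the genotypes at 24 h and 14% at 7 d. The interaction tests recovered 7%, 4%, 5% and 0% at 6 h, 24 h, 48 h and 7 d. Changes of that size can therefore go uncalled, and a 0 count does not show their absence.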

Other observations

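The test of sex was a term of the planned model, and its genes were examined after the data were seen. Sex had a wide effect on these livers, with 558 genes that differed between males and females, 251 higher in males and 307 higher in females, of which 530 lay on autosomes. Genes higher in males included the urinary protein gene Mup20 by 6.53 (SE 0.39), the fatty acid hydroxylase gene Cyp4a12a by 9.16 (SE 0.64), the elongase gene Elovl3 by 5.61 (SE 0.47) and the oxysterol hydroxylase gene Cyp7b1 by 4.04 (SE 0.27) on the log2 scale. Among genes higher in females, Cyp2b13 and the sulfotransferase gene Sult2a1 had no counts in most males, so no fold is given for them. Nox4 itself was higher in males by 3.58 (SE 0.34), a difference larger than that between the genotypes averaged over stages (-2.82, SE 0.28). Since the groups hold unequal numbers of males and females, a comparison of genotypes by raw means mixes sex with genotype.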
